A study of Homo sapiens with 12 samples.

How the data were processed

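RNA-seq read counts were studied for 12 libraries of HEK293T cells in 4 groups of 3: individual aptamers or the dual-specificity aptamer, each without and with Wnt. Per the labels, cells were transfected with 1.5 µg of aptamer plasmid, the medium was replaced at 20 h with fresh DMEM or DMEM holding 50% Wnt3A-conditioned medium, and the cells were harvested at 24 h, so the exposure lasted 4 h. Per the submitters' processing notes, Trim Galore, HISAT2, featureCounts and DESeq2 were used with GRCh38.p13; their versions, settings and order and the gene annotation are not stated.

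The deposited count table holds raw counts per Ensembl gene ID as whole numbers, with no normalisation, for 60683 genes. The authors also deposited a table of DESeq2 output for the aptamer comparison in each medium. Per the file headers, baseMean in the deposited tables is a signal, the mean of size-factor-normalised counts; it is identical in both tables, so both came from 1 fit of all libraries. The deposited fold changes and their standard errors are on the log2 scale. The deposited Wald statistic is a score, the log2 fold change divided by its standard error. The deposited p-value columns hold the p and the Benjamini-Hochberg adjusted p, which 24332 genes had without Wnt and 23149 with Wnt. Every count column was used.

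Gene symbols were found for 42013 of the IDs, among them 15921 (89.3%) of the tested genes, and 17532 tested genes had a span in GENCODE release 29, from which all positions were taken. Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr by group (minimum count 10, minimum total 15), which left 17838, and libraries were scaled by TMM. A model with 1 mean per group was fitted to all 12 libraries with robust quasi-likelihood dispersions, and genes with a Benjamini-Hochberg adjusted p below 0.05 in the two-sided quasi-likelihood F test were called. CPM values, from edgeR's cpm, are counts scaled to the TMM-corrected library size. Errors of CPM values are SDs over the 3 libraries of a group, and errors of log2 fold changes are standard errors from the fit.

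The comparisons were the aptamer effect without Wnt, the aptamer effect with Wnt, the Wnt effect with individual aptamers, the Wnt effect with the dual aptamer, the aptamer effect averaged over media, the Wnt effect averaged over aptamers, and the aptamer by Wnt interaction. In the aptamer comparisons a positive log2 fold change is higher with the dual aptamer, in the Wnt comparisons higher with conditioned medium, and the interaction is the aptamer effect with Wnt minus that without. The comparisons, tests, 31 gene lists and the rule for named genes were fixed before the data were examined. Lists were tested with camera (preset correlation 0.01, two-sided, adjusted over the lists of a comparison), with camera using an estimated correlation, and with fry, which asks whether a list's genes move one way on balance and compares them with no other genes. The lists were core Wnt targets, other reported Wnt targets, Wnt pathway machinery, cadherin and catenin adhesion, O-GlcNAc and hexosamine pathway, PRC2 complex, interferon and RNA sensing, NF-kappaB and inflammation, integrated stress response, endoplasmic reticulum chaperones, heat shock response, immediate early genes, p53 targets, sterol synthesis, hypoxia and glycolysis, MondoA targets, TGF-beta and BMP targets, YAP and SRF targets, G1/S and G2/M cell cycle, replication-dependent histones, cytosolic ribosomal proteins, ribosome biogenesis, mitochondrially encoded messenger RNAs, nuclear oxidative phosphorylation, fibroblast, blood cell and epithelial markers, nuclear long noncoding RNAs, vitamin and retinoid response, and HOX genes.

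The rule for named genes took, in each pairwise comparison, called genes with a symbol, a mean of at least 1 CPM in at least 1 of the groups and no overlap between their libraries, up to 10 with the largest fold change in each direction. It added up to 8 called members per list by smallest p, 9 core Wnt targets (AXIN2, NKD1, LEF1, SP5, RNF43, ZNRF3, LGR5, NOTUM and TNFRSF19), CTNNB1, OGT and OGA whether called or not, and up to 10 interaction genes by smallest p; where fewer than 5 genes passed, the 5 of smallest p were named with their outcome. Near-silent genes were those on the autosomes and the X chromosome with a mean over all 12 libraries below 0.5 CPM, here scaled to the total count without TMM, and expressed genes those with a mean of at least 10 CPM.

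The alternatives were DESeq2 size factors and upper-quartile factors in the edgeR test, DESeq2 1.42.0 on all libraries, no low-count filter, the replicate number as a block, the 6 compared libraries alone, a fold change of at least 1.5, and leaving out each library in turn. Chosen after seeing the data were a test of genes of at least 10 CPM alone, subtraction of the near-silent gene level by span, offsets for GC content and transcript length, and medium comparisons between groups closer in near-silent level. The subtraction took each library's level above that of the lowest library from the counts, in proportion to span and at 1 rate for all genes. Fewer calls of long, weakly expressed genes after it are thus partly built in. The calling of the aptamer effect without Wnt was tested on simulated data, with library sizes, mean levels and spread from the fit of all 12 libraries. Of 50 genes each changed 1.1-, 1.2-, 1.5- and 2-fold, 18%, 60%, 66% and 92% were called, with 3 false calls among 17638 unchanged genes. Of lists, 5 of 5 raised by 0.15 (log2) and 0 of 20 unchanged ones were called. Changed genes were drawn above a minimum mean count and list genes above a higher one, so recovery nearer the floor was not tested. Genes were simulated independently, so false calls of lists of correlated genes were not tested either. Confidence intervals of fold changes are 95% intervals from the fit. Reads without molecular identifiers are not independent molecules. The interval of a share is taken over genes and treats them as independent. Genes on the Y chromosome were not reported, and reads were not realigned since none were available here. Some genes that the rule names are not reported here.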

Results

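RNA was sequenced from HEK293T cells, a human embryonic kidney cell line that carries the SV40 large T antigen, after transfection with plasmids that express RNA aptamers. The dual-specificity aptamer 3JB8F+12 was compared with the individual aptamers T1 and bc339 expressed as the control. Per the series title the dual aptamer raises O-GlcNAcylation on beta-catenin, the coactivator of Wnt target genes. Each aptamer was studied in fresh medium (without Wnt) and in medium of which 50% was conditioned by Wnt3A-producing cells (with Wnt), applied for the last 4 h before harvest. The 4 groups held 3 libraries each. Total counts per library were 20354227 to 22387535 for individual aptamers without Wnt and 19554972 to 20543774 for the dual aptamer without Wnt. With Wnt they were 19371946 to 19922911 for individual aptamers and 20815601 to 23887181 for the dual aptamer. Nothing in the labels shows that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples. That spread was small, with a biological coefficient of variation of 2.61%.

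The counts came from the deposited table, and 17838 of its 60683 genes had enough counts to be tested. Among coding genes that lie inside an intron of another coding gene, 411 of 414 (99.3%) had a count of 0 in every library, against 1184 of 13296 (8.90%) of coding genes that overlap no coding gene. Of 1804 coding genes fully overlapped by other genes, 1721 (95.4%) were at 0. These values are those of counting over whole gene spans with reads in overlapping parts left out, although the labels do not state the rule. The Wnt targets RNF43 and SP5, the immediate early genes JUNB and DUSP1, the heat shock gene HSPE1, the ribosomal protein gene RPL32 and the interferon gene IFIT1 had a count of 0 in all libraries. Except for SP5, which overlaps no gene, their whole span is overlapped, so their expression could not be measured. AXIN2 was counted over 28.8% of its span, SENP3 over 13.99% and TAF15 over 36.4%.

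Some measures of the libraries as a whole moved with the groups. Genes with a mean below 0.5 CPM (counts scaled to the library size), here called near-silent, were counted at 3.99 ± 0.05 CPM per megabase of span that no other gene overlaps (SD, n = 3) for individual aptamers without Wnt and at 5.38 ± 0.11 for the dual aptamer without Wnt. With Wnt the order was the opposite, at 4.88 ± 0.21 for individual aptamers and 3.80 ± 0.05 for the dual aptamer. The number of genes with at least 1 count followed, with means of 24626, 25971, 25688 and 24649 in the same order. Mitochondrially encoded transcripts took 6.53 ± 0.113% of the counts for individual aptamers and 6.35 ± 0.0950% for the dual aptamer without Wnt, and 6.07 ± 0.0471% and 6.05 ± 0.126% with Wnt.

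**Figure D1:**
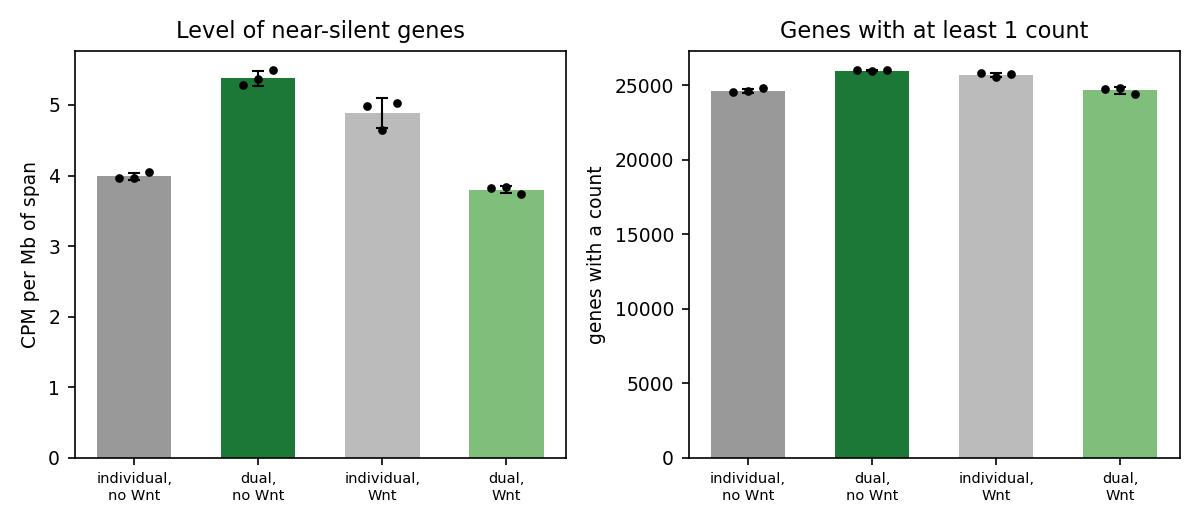
CPM per megabase of near-silent genes (left) and the number of genes with at least 1 count (right) for each of the 12 libraries (points), with group means as bars and SD as error bars (n = 3). Dual aptamer libraries without Wnt (mean 5.38) and individual aptamer libraries with Wnt (mean 4.88) lie above the libraries of the other groups (means 3.99 and 3.80).

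The comparison of Wnt3A-conditioned with fresh medium, averaged over the aptamers, asks how the cells responded to the medium. AXIN2, the feedback inhibitor that is among the most general targets of beta-catenin, rose from 16.2 ± 0.998 CPM to 57.4 ± 2.81 CPM with individual aptamers and from 16.5 ± 0.131 to 56.6 ± 2.21 with the dual aptamer (SD, n = 3 each). Its log2 fold change was 1.80 (SE 0.04), a 3.49-fold rise, with an edgeR adjusted p of 5.11e-43. TNFRSF19, a receptor gene activated by beta-catenin with TCF factors, rose 2.30-fold (SE 0.04 on the log2 scale). The secreted inhibitor DKK1 rose by 1.46 (SE 0.09) on the log2 scale, as do all later rises and falls given without a unit. The feedback gene NKD1 rose by 0.91 (SE 0.06) and the transcription factor genes CDX2 and TCF7 by 0.91 and 0.67. The stem cell receptor LGR5 rose by 0.46 (SE 0.05), the ubiquitin ligase ZNRF3 by 0.36 (SE 0.03) and LEF1, a DNA-binding partner of beta-catenin, by 0.31 (SE 0.03). Of the 24 tested core Wnt targets, 17 rose and 3 fell, and adjusted over the list alone 18 rose and 3 fell. The list's median log2 fold change was 0.41, and camera gave an adjusted p of 6.63e-22 with the preset and 0.000129 with an estimated correlation. NOTUM, which encodes a secreted Wnt deacylase, had a log2 fold change of -0.11 (adjusted p = 0.454). AXIN2 lies at chromosome 17, 65528563 to 65561647 (ENSG00000168646), and TNFRSF19 at chromosome 13, 23570370 to 23676104 (ENSG00000127863). NKD1 lies at chromosome 16, 50548330 to 50649249 (ENSG00000140807) and LEF1 at chromosome 4, 108047545 to 108168956 (ENSG00000138795), in GRCh38 as for all positions here.

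**Figure D2:**
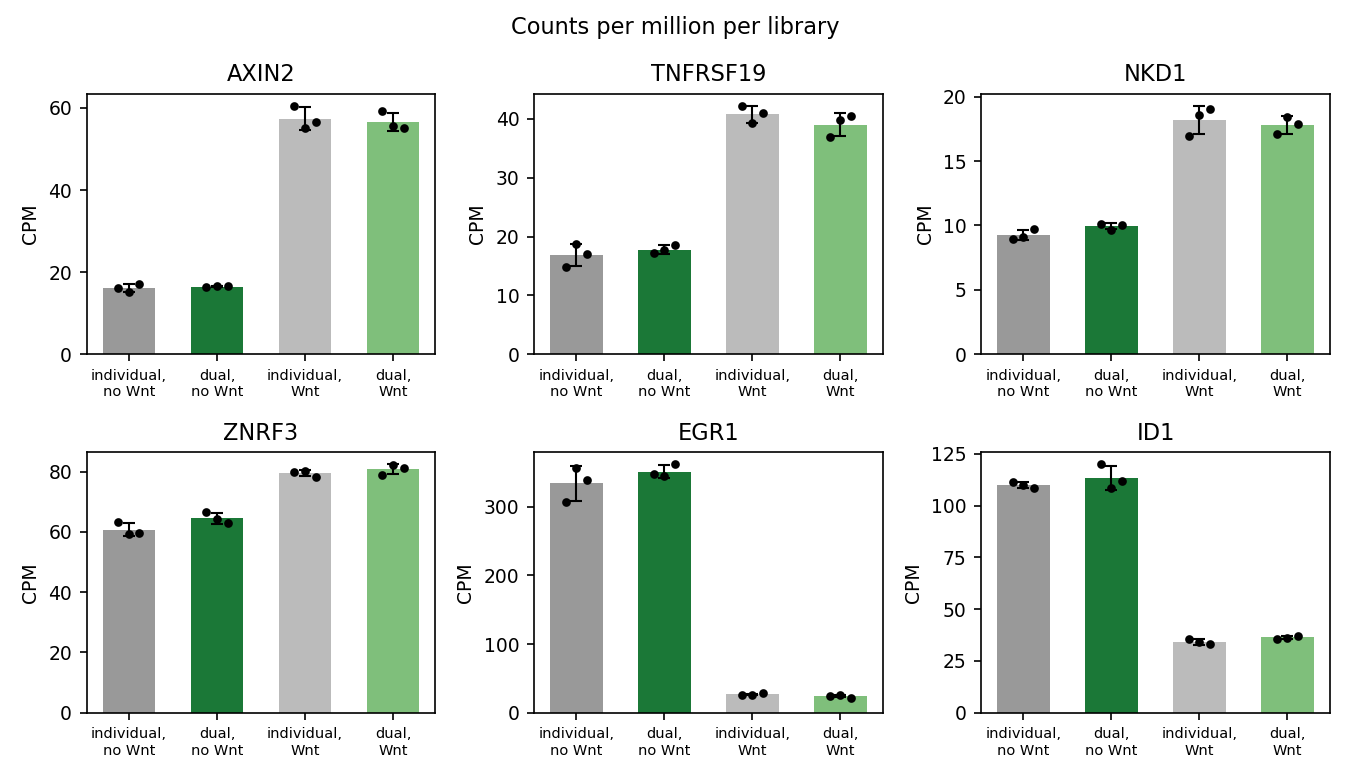
Expression in CPM of AXIN2, TNFRSF19, NKD1, ZNRF3, EGR1 and ID1 in each library; bars are group means with SD (n = 3) and points are libraries. AXIN2 lies at 16.2 and 16.5 CPM without Wnt and at 57.4 and 56.6 CPM with Wnt, individual aptamers first, while EGR1 falls from 334 and 351 to 26.6 and 23.7 CPM.

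Among the genes around beta-catenin and O-GlcNAc, CTNNB1, the beta-catenin gene (ENSG00000168036, chromosome 3, 41194741 to 41260096), had a log2 fold change of 0.02 (95% confidence interval -0.02 to 0.06, adjusted p = 0.452), whose sign upper-quartile scaling turned. OGT, which adds O-GlcNAc to proteins (ENSG00000147162, chromosome X, 71533083 to 71575897), rose by 0.10 (SE 0.02). Between groups closer in near-silent gene level, compared after seeing the data, it did not pass for the dual aptamer with Wnt over individual aptamers without Wnt (0.03, adjusted p = 0.427) but did for individual aptamers with Wnt over the dual aptamer without Wnt (0.16). OGA, which removes it (ENSG00000198408, chromosome 10, 101784443 to 101818465), rose by 0.11 (SE 0.02). Of 14 tested O-GlcNAc and hexosamine pathway genes, 7 rose and none fell, with GFPT2 at 0.32. The list's call (camera adjusted p = 0.0451) had adjusted p = 0.117 with an estimated correlation. Of 37 tested genes of the Wnt pathway machinery, 10 rose and 14 fell, among them the receptors FZD1 (-0.55) and FZD5 (-0.47) and the corepressor TLE1 (-0.35), while upper-quartile scaling gave 3 higher and 18 lower and DESeq2 size factors 7 and 14. Camera gave adjusted p = 0.0223, and adjusted p = 0.0638 with an estimated correlation. Of 12 cadherin and catenin adhesion genes, 5 rose and 2 fell, with vinculin (VCL, 0.39), nectin-2 (NECTIN2, 0.33) and TJP1 (0.31) higher (camera adjusted p = 0.00424, and adjusted p = 0.0961 with an estimated correlation). Of 29 other reported Wnt targets, 11 rose, such as cyclin D1 (CCND1, 0.62), WNT11 (0.76) and CLDN1 (0.82), and 9 fell, such as JUN (-1.16), SOX4 (-0.75) and ID2 (-0.73). That list was not called (camera adjusted p = 0.183). Its median of 0.02 and its mean were above 0 while its test pointed down, and with upper-quartile scaling its median turned below 0, with 9 higher and 10 lower. Of 12 PRC2 complex genes, 5 rose, with JARID2 at 0.26, and 2 fell, with EZH2 at -0.11 (camera adjusted p = 0.368), and upper-quartile scaling turned the list's median of 0.03 below 0, with 2 higher and 3 lower.

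Among the 31 lists, the largest shift was a fall of immediate early genes, which serum and growth factors switch on within minutes. EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315) fell by 3.77 on the log2 scale (SE 0.04, adjusted p = 1.04e-33), from 334 ± 25.6 to 26.6 ± 1.4 CPM with individual aptamers and from 351 ± 9.3 to 23.7 ± 1.47 CPM with the dual aptamer. FOS (ENSG00000170345, chromosome 14, 75278774 to 75282230) fell by 3.64 (SE 0.06), EGR2 by 2.96, IER2 by 1.43 and NR4A2 by 1.29. Of 28 tested members 23 fell and 2 rose, IER3 (1.24) and the phosphatase gene DUSP4 (0.97). The median was -0.72, with a camera adjusted p of 4.4e-77 and of 0.000199 with an estimated correlation. Targets of TGF-beta and BMP fell as well. ID1 (ENSG00000125968, chromosome 20, 31605283 to 31606515), a BMP target that inhibits differentiation factors, fell by 1.66 (SE 0.03), ID3 by 1.33, ID4 by 1.01 and the inhibitory SMAD6 by 0.63. The ligand genes BMP4 and BMP2 (0.68) rose. In that list 14 of 22 fell and 5 rose (camera adjusted p = 2.82e-17, and adjusted p = 0.0233 with an estimated correlation). Of 22 tested p53 targets 19 fell and none rose, among them MDM2 (-0.59), GADD45A (-0.49) and BBC3 (-0.44), with a median of -0.18 (camera adjusted p = 1.66e-15, and adjusted p = 0.0437 with an estimated correlation).

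Heat shock genes rose with the conditioned medium. The constitutive chaperone HSPA8 (ENSG00000109971, chromosome 11, 123057489 to 123063230) rose from 352 ± 9.15 to 784 ± 30.1 CPM with individual aptamers and from 340 ± 5.19 to 740 ± 24.3 CPM with the dual aptamer, a log2 fold change of 1.14 (SE 0.02). The inducible HSPA1A rose by 1.12 and the cochaperones DNAJA1 by 0.78 and DNAJB1 by 0.62, the last counted over 15.4% of its span. Of 18 tested heat shock genes 13 rose and 1 fell (median 0.23, camera adjusted p = 1.18e-17, and adjusted p = 0.0392 with an estimated correlation). Chaperones of the endoplasmic reticulum moved the other way, with 12 of 20 lower and none higher, among them HERPUD1 (-0.70) and HSPA5 (-0.16), the main chaperone of that compartment (camera adjusted p = 0.00382, and adjusted p = 0.0437 with an estimated correlation). Of 22 integrated stress response genes 13 fell, such as the regulator ATF4 (-0.33), and 3 rose, with STC2 at 0.68 (camera adjusted p = 0.00227, and adjusted p = 0.155 with an estimated correlation).

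Of 29 tested G2/M cell cycle genes 21 rose and none fell, for instance MKI67 (0.24), AURKA (0.25) and CCNB1 (0.22), with a median of 0.09 (camera adjusted p = 7.33e-05, and adjusted p = 0.0437 with an estimated correlation); with upper-quartile scaling 16 rose and 2 fell. Of 22 replication-dependent histone genes 11 fell and none rose, with H2BC21 at -0.90 and H2AC6 at -0.58 (camera adjusted p = 0.00176, and adjusted p = 0.0437 with an estimated correlation). Of 30 G1/S genes 12 rose, such as CDC6 (0.20), and 2 fell, among them the licensing factor CDT1 (-0.39), against 9 and 6 with upper-quartile scaling, and the list was not called (camera adjusted p = 0.183). Of 21 ribosome biogenesis genes 16 rose and 2 fell, with the pseudouridine synthase DKC1 at 0.31 and ODC1 at -0.27 (camera adjusted p = 2.5e-05, and adjusted p = 0.325 with an estimated correlation). Of 56 cytosolic ribosomal protein genes 37 fell, with RPL3 at -0.13, and 1 rose (camera adjusted p = 0.000914, and adjusted p = 0.638 with an estimated correlation), while upper-quartile scaling gave 51 lower and 1 higher. Of 13 mitochondrially encoded messenger RNAs 9 fell, with MT-ND1 at -0.16, and none rose (camera adjusted p = 0.0068, and adjusted p = 0.331 with an estimated correlation), beside the lower mitochondrial share of the counts with Wnt. The fall lay mostly with individual aptamers, where the list's median was -0.12, against -0.01 with the dual aptamer. With upper-quartile scaling the medians were -0.14 and -0.06, with 12 and 6 members lower, so the near absence of a fall with the dual aptamer depended on the scaling. Of 7 nuclear long noncoding RNAs 5 fell and none rose, with NEAT1 at -0.49 and MALAT1 at -0.32 (camera adjusted p = 0.00791, and adjusted p = 0.0948 with an estimated correlation).

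Further lists changed in part. Of 27 sterol synthesis genes 12 fell, such as INSIG1 (-0.46) and SREBF1 (-0.44), and 3 rose (camera adjusted p = 0.000914, and adjusted p = 0.13 with an estimated correlation). Of 17 NF-kappaB and inflammation genes 8 rose, with the chemokine CCL2 at 0.57 and NFKB1 at 0.35, and 2 fell (camera adjusted p = 0.0231, and adjusted p = 0.0948 with an estimated correlation). Of 21 YAP and SRF targets 10 rose, with AJUBA at 1.21, LATS2 at 0.50 and ACTB at 0.22, and 5 fell (camera adjusted p = 0.0451, and adjusted p = 0.325 with an estimated correlation). Of 19 HOX genes 7 fell, with HOXD10 at -0.39 and HOXD13 at -0.42, and 3 rose (camera adjusted p = 0.0451, and adjusted p = 0.175 with an estimated correlation).

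The lists that follow were not called by camera. Of 31 hypoxia and glycolysis genes 6 rose, among them the glucose transporters SLC2A3 (1.60) and SLC2A1 (0.34), and 11 fell, with BHLHE40 at -0.62 (adjusted p = 0.345). The median of -0.01 was below 0 while the mean and the test pointed up. Of 6 glucose-sensing MondoA targets ARRDC4 (1.01) and TXNIP (0.24) rose and 3 fell, with ARRDC3 at -0.77 (adjusted p = 0.726), where the median of -0.10 was below 0 while the mean and the test pointed up. Of 25 interferon and RNA sensing genes 7 rose, with IFIT5 at 0.33, and 4 fell, with ISG15 at -0.48 (adjusted p = 0.99), with a median of -0.04 and a test that pointed up, and upper-quartile scaling gave 5 higher and 8 lower. Of 7 vitamin and retinoid response genes 2 fell, RARB (-0.45) and CYP26B1 (-0.28), and none rose (adjusted p = 0.646). Of 28 nuclear oxidative phosphorylation genes ATP5F1D rose by 0.08, adjusted over the list alone none was called (adjusted p = 0.728), and with upper-quartile scaling none rose and 5 fell. Markers of other cell types changed in few members. Of 8 fibroblast markers COL3A1 (0.34) and LUM (0.78) rose and VIM (-0.17) fell (adjusted p = 0.88). Of 7 epithelial markers KRT18 (0.28) and KRT19 (0.10) rose (adjusted p = 0.647), and of 3 blood cell markers NKG7 (-0.88) fell (adjusted p = 0.728). Between individual aptamers with Wnt and the dual aptamer without Wnt, groups closer in near-silent level, LUM (0.52, adjusted p = 0.145), KRT18 (0.24, 0.136) and KRT19 (0.09, 0.0696) did not pass. Some calls also ended without 1 library. CYP26B1 lost its call (adjusted p from 0.0572 to 0.0936) without replicate 3 of individual aptamers without Wnt, replicates 2 and 3 of the dual aptamer without Wnt, replicates 2 and 3 of individual aptamers with Wnt or replicate 1 of the dual aptamer with Wnt. ATP5F1D lost it without replicate 2 of individual aptamers without Wnt (adjusted p = 0.0802), replicate 2 of the dual aptamer without Wnt (0.104) or replicate 1 of the dual aptamer with Wnt (0.0855). NKG7 lost it without replicates 1 and 2 of individual aptamers without Wnt, replicate 2 of the dual aptamer without Wnt, any replicate of individual aptamers with Wnt, or replicates 2 and 3 of the dual aptamer with Wnt (adjusted p from 0.0582 to 0.295). Without replicate 2 of the dual aptamer without Wnt its value was -0.55.

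**Figure D3:**
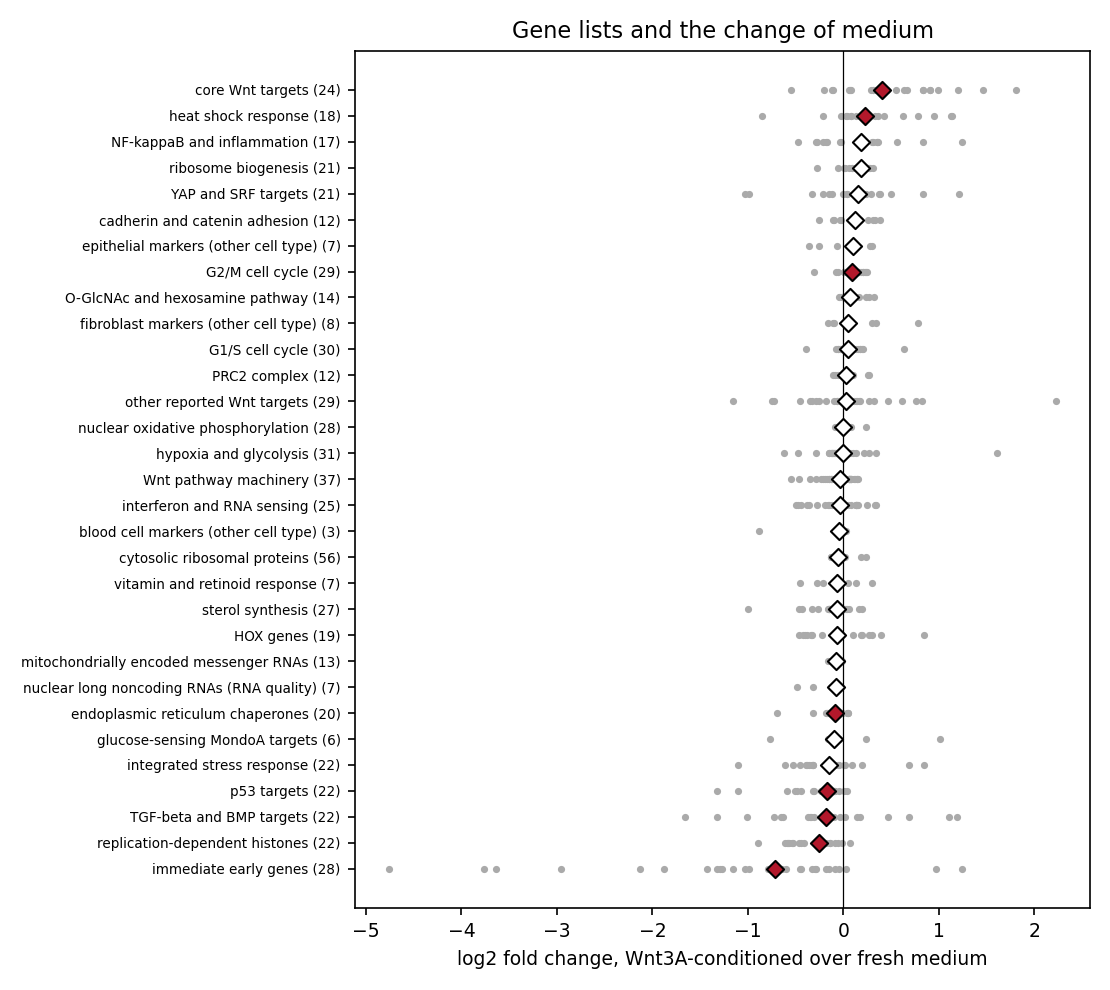
Log2 fold change of Wnt3A-conditioned over fresh medium, averaged over aptamers, for each member of the 31 gene lists (grey points), with the list median as a diamond that is red where camera with an estimated correlation gave an adjusted p below 0.05, and the number of tested genes in brackets. Core Wnt targets (median 0.41) and heat shock genes (0.23) lie to the right and immediate early genes (-0.72) to the left; upper-quartile scaling turned the medians of other reported Wnt targets and of PRC2 genes below 0.

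In the edgeR quasi-likelihood test 7038 of 17838 genes were called in this comparison, 3726 higher and 3312 lower with Wnt, and 174 of them changed at least 2-fold. Upper-quartile scaling gave 2865 higher and 4410 lower, so the balance of directions depended on the scaling. Of the calls, 52.9% were higher with the reported scaling and 39.4% with upper-quartile scaling. A fold change of at least 1.5 left 302 higher and 423 lower, and among genes of at least 10 CPM 3117 were higher and 2144 lower. Adjusted over the list alone, the higher and lower counts became 12 and 10 for other reported Wnt targets, 11 and 14 for the Wnt machinery, 5 and 3 for PRC2, 7 and 5 for interferon genes, 8 and 3 for NF-kappaB genes and 3 and 15 for the integrated stress response. They became 0 and 20 for p53 targets, 12 and 3 for G1/S, 22 and 1 for G2/M, 1 and 39 for ribosomal proteins, 0 and 11 for mitochondrially encoded messenger RNAs and 2 and 3 for the retinoid list, and apart from core Wnt targets and oxidative phosphorylation the other lists kept their counts. Camera called 20 of the 31 lists with the preset correlation and 8 with an estimated one, namely core Wnt targets, immediate early genes, TGF-beta and BMP targets, heat shock genes, endoplasmic reticulum chaperones, p53 targets, G2/M genes and histones. Between groups closer in near-silent gene level, a comparison chosen after seeing the data, 5146 genes were called for the dual aptamer with Wnt over individual aptamers without Wnt and 4623 for individual aptamers with Wnt over the dual aptamer without Wnt. The level still differed without overlap between libraries (means of 3.80 against 3.99 and of 4.88 against 5.38 CPM per megabase), and the aptamer differed too. The conditioned and the fresh medium differ in more than Wnt3A, and no control-conditioned medium was sequenced.

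Taken for each aptamer alone, the medium comparison asks how the cells responded with the control and with the dual aptamer. With individual aptamers, CYP1A1, a xenobiotic-metabolising enzyme gene, rose by 3.46 (SE 0.13) and the ETS factor ETV5 by 2.94 (SE 0.10). AXIN2 rose by 1.83 (SE 0.06), DKK1 by 1.50, TNFRSF19 by 1.27 and NKD1 by 0.97. EGR3 fell by 4.91 (SE 0.41; counted over 44.1% of its span), EGR1 by 3.65, EGR2 by 2.89, CALD1 by 2.41 and DUSP5 by 2.14. The named rises also held long, weakly expressed genes, namely AGBL1 (4.38), LINC03000 (3.82), PTPRT (3.76), CTNNA2 (3.17), CDH18 (3.03) and CSMD1 (2.99), in libraries whose near-silent gene level was higher with Wnt. Of 17838 genes 4792 were called by edgeR, 2645 higher and 2147 lower, against 2256 higher and 2654 lower with upper-quartile scaling and 549 higher and 302 lower at a fold change of at least 1.5. Among genes of at least 10 CPM, 1997 were higher and 1642 lower. Of the core Wnt targets 17 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000261 with an estimated correlation). Camera called 17 lists with the preset and 8 with an estimated correlation.

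With the dual aptamer, CYP1A1 rose by 3.52 (SE 0.13), ETV5 by 3.18 (SE 0.10), the related ETV1 by 2.16, EDN1, which encodes endothelin, by 2.39 (SE 0.37), the phosphate hormone gene STC1 by 1.78 and AXIN2 by 1.78 (SE 0.06). EGR3 fell by 4.61 (SE 0.37), FOS by 3.88 and EGR1 by 3.88. Here the long, weakly expressed genes fell, among them NRG3 (-3.87), LRRC4C (-3.50), SEMA5A (-3.44), PTPRT (-3.32), AGBL1 (-3.26) and RBFOX1 (-3.18), in libraries whose near-silent gene level was lower with Wnt. Of 17838 genes 5557 were called by edgeR, 2933 higher and 2624 lower, so that 52.8% were higher, against 35.3% (1999 higher and 3671 lower) with upper-quartile scaling and 24.0% (279 higher and 882 lower) at a fold change of at least 1.5. Among genes of at least 10 CPM, 2596 were higher and 1376 lower. Of the core Wnt targets 16 rose and 2 fell, and adjusted over the list alone 17 rose and 2 fell (camera adjusted p = 0.000218 with an estimated correlation). Camera called 18 lists with the preset and 5 with an estimated correlation. For the cadherin and catenin list (camera adjusted p = 0.0441, and adjusted p = 0.231 with an estimated correlation) the median of 0.05 and the test pointed up while the mean of -0.16, which CTNNA2 enters, was below 0.

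Both medium comparisons called 3515 genes, of which 1914 rose in both and 1370 fell in both, against 435 and 316 if the calls were independent. The other 231 rose with individual aptamers and fell with the dual aptamer, where 389 were expected by that count. All 231 were also called in the test of the difference, which opposite calls from the same fit nearly ensure. None had a mean of 10 CPM or more, and their median span was 476 kb. Among the 10110 genes with a mean of at least 10 CPM, 2788 were called in both, 1721 higher and 1067 lower, with a correlation across genes of r = 0.93 (Spearman rho = 0.86), while across all tested genes it was r = -0.03 (rho = 0.51). Genes are not independent replicates, and the compared pairs of groups share no library.

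The aptamer comparison without Wnt asks what the dual aptamer changed in cells in fresh medium. Most genes that rose were long genes near the detection limit, several of them known for roles in neurons. AGBL1 (ENSG00000273540, chromosome 15, 86079973 to 87029052) rose from 0.0455 ± 0.0446 to 1.2 ± 0.173 CPM (SD, n = 3; log2 fold change 4.51, SE 0.55), and PTPRT, a receptor phosphatase gene (ENSG00000196090, chromosome 20, 42072752 to 43189970), from 0.122 ± 0.09 to 1.55 ± 0.365 CPM (3.57, SE 0.41). LINC03000 (4.12), SGCD (3.34), the neuronal catenin CTNNA2 (3.30), LINC02055 (3.12), GALNT17 (2.89), SEMA5A (2.89), CCDC26 (2.87) and CA10 (2.84) also rose. Of the 214 genes that rose, 211 had a mean below 10 CPM and their median span was 523 kb, against 32.4 kb for all tested genes. Their median level was 0.212 CPM with individual aptamers and 0.999 CPM with the dual aptamer. Among expressed genes the immediate early gene FOS rose from 34.2 ± 1.43 to 42.7 ± 2.06 CPM (0.32, SE 0.06, edgeR adjusted p = 0.000133).

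The 7 genes that fell without Wnt changed by little: ALG6 (-0.16), CD109 (-0.14), the fibronectin gene FN1 (-0.14), the cytoskeletal scaffold IQGAP1 (-0.13), the complex I genes MT-ND5 (-0.12) and MT-ND6 (-0.11), and the ribonucleotide reductase gene RRM1 (-0.11). Each lost its call without at least 1 library. Without replicate 2 of individual aptamers without Wnt the adjusted p was 0.209 for ALG6, 0.159 for CD109, 0.247 for FN1, 0.145 for IQGAP1 and 0.0839 for RRM1. Without replicate 2 of the dual aptamer without Wnt it was 0.156 for ALG6, 0.0713 for CD109, 0.109 for FN1, 0.102 for RRM1, 0.102 for MT-ND5 and 0.0516 for MT-ND6. ALG6 also lost it without replicate 3 of individual aptamers (0.116) or of the dual aptamer (0.0506), CD109 without replicate 1 of individual aptamers (0.0809) or of the dual aptamer (0.131), FN1 without the same replicates (0.0625 and 0.0944), and RRM1 without replicate 1 of individual aptamers (0.144) or replicate 3 of the dual aptamer (0.168).

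The Wnt targets did not pass the test in fresh medium. AXIN2 had a log2 fold change of 0.03 (95% confidence interval -0.11 to 0.17, adjusted p = 0.958), TNFRSF19 of 0.07 (0.86), NKD1 of 0.10 (0.837), ZNRF3 of 0.09 (0.495), LEF1 of -0.06 (0.815), LGR5 of -0.01 and NOTUM of -0.01. CTNNB1 was at -0.06 (0.536), OGT at -0.05 (0.675) and OGA at -0.02 (0.915). None of the 24 core Wnt targets was called by edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.682). Camera called 6 lists with the preset and none with an estimated correlation, where the smallest adjusted p was 0.389. Fry called none. The called lists were mitochondrially encoded messenger RNAs (median -0.06, adjusted p = 2.15e-05, and adjusted p = 0.414 with an estimated correlation), G1/S genes (-0.02; 0.000938 and 0.607), cytosolic ribosomal proteins (0.02; 0.00975 and 0.958), G2/M genes (-0.04; 0.0123 and 0.389), immediate early genes (0.05; 0.017 and 0.607) and PRC2 genes (-0.03; 0.0249 and 0.389). In all 221 of 17838 genes were called by edgeR, 214 higher and 7 lower, and 186 of them at least 2-fold. The lower count depended on single libraries, at 79 (beside 212 higher) without replicate 1 of the dual aptamer without Wnt and at 3 (beside 183) without its replicate 2. With the near-silent gene level subtracted by the span that no other gene overlaps, 21 genes were called, and when the test was run on the 10110 genes of at least 10 CPM, 2 were called, FOS among them. Both alternatives were chosen after seeing the data. Since the subtraction removes counts in proportion to span, fewer calls of long, weakly expressed genes after it are partly built in.

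The aptamer comparison with Wnt asks what the dual aptamer changed under Wnt3A-conditioned medium. The long, weakly expressed genes now fell. RBFOX1, a neuronal splicing factor gene (ENSG00000078328, chromosome 16, 5239802 to 7713338), fell from 5.98 ± 1.83 to 0.704 ± 0.0315 CPM (SD, n = 3; log2 fold change -3.07, SE 0.23), and NRG3 (ENSG00000185737, chromosome 10, 81875314 to 82987179) from 1.99 ± 0.833 to 0.137 ± 0.0546 CPM (-3.83, SE 0.39). LRRC4C (-3.59), PTPRT (-3.52), AGBL1 (-3.13), ADGRB3 (-3.09), RELN (-3.04), FRMPD4 (-2.86), LUZP2 (-2.84) and CTNNA2 (-2.81) fell as well. Of the 201 genes that fell, 192 had a mean below 10 CPM, with a median span of 530 kb. Of the 27 genes that rose, 23 had a mean of at least 10 CPM, and their median span was 17.2 kb. Among them the SUMO protease gene SENP3 (ENSG00000161956, chromosome 17, 7561875 to 7571969) rose by 0.28 (SE 0.05, edgeR adjusted p = 0.000795), UBE2M, the conjugating enzyme for NEDD8 (ENSG00000130725, chromosome 19, 58555712 to 58558960), by 0.21 (SE 0.04, 0.000969) and FBXL19 (ENSG00000099364, chromosome 16, 30923055 to 30948783) by 0.19 (SE 0.04, 0.000613). UBE2M went from 186 ± 0.84 to 215 ± 12 CPM and FBXL19 from 92.0 ± 1.12 to 105 ± 3.51 CPM. HIRIP3 (0.20) and TAF15 (0.20) lost their calls without replicate 1 of the dual aptamer with Wnt (adjusted p = 0.0786 and 0.0749), and the rRNA methyltransferase gene FBL (0.18) without that library (0.0952) or replicate 3 of individual aptamers with Wnt (0.0926).

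AXIN2 was at -0.02 with Wnt (95% confidence interval -0.11 to 0.07, adjusted p = 0.939), TNFRSF19 and LEF1 at -0.06 and 0.06, LGR5 at -0.12 (0.595), NKD1 at -0.03, ZNRF3 at 0.02 and NOTUM at -0.03. CTNNB1 was at -0.02 (0.864), OGT at -0.07 (0.413) and OGA at -0.02 (0.897). None of the 24 core Wnt targets was called by edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.815). Camera called 10 lists with the preset, 9 higher and 1 lower, and none with an estimated correlation, where the smallest adjusted p was 0.574. Fry called none. They included cytosolic ribosomal proteins (median 0.04, adjusted p = 7.33e-08, and adjusted p = 0.652 with an estimated correlation), nuclear oxidative phosphorylation (0.05; 6.72e-05 and 0.574), the integrated stress response (0.07; 0.00132 and 0.574), TGF-beta and BMP targets (0.06; 0.00176 and 0.574) and the cadherin and catenin list (-0.02; 0.0169 and 0.574), whose single called member was CTNNA2. Adjusted over the list alone, 1 integrated stress response gene and 2 TGF-beta and BMP targets were higher. In all 228 of 17838 genes were called by edgeR, 27 higher and 201 lower, and 176 of them at least 2-fold. The higher count was 9 without replicate 1 of the dual aptamer with Wnt, 37 without its replicate 2, and 54 with the replicate number as a block. With the near-silent gene level subtracted by the span that no other gene overlaps, 19 were called. When the edgeR test was run on the 10110 genes of at least 10 CPM, none was called (768 at an unadjusted p below 0.05), and the adjusted p of SENP3, UBE2M and FBXL19 was 0.0795 each. In the reported fit the adjusted p of these genes also depended on the p of the weakly expressed genes. DESeq2 on all genes called 102.

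Averaged over the media, the comparison asks what the dual aptamer changed in both. The cytoskeletal scaffold gene IQGAP1 (ENSG00000140575, chromosome 15, 90388218 to 90502243) was lower with the dual aptamer, at 286 ± 7.89 and 261 ± 5.75 CPM without Wnt and 282 ± 10.9 and 264 ± 10.5 CPM with Wnt (SD, n = 3; individual aptamers first). Its log2 fold change was -0.11 (SE 0.02, edgeR adjusted p = 0.0455). The nonmuscle myosin gene MYH10 (-0.12, SE 0.02, 0.0455) and DSP, a desmosome component (-0.11, SE 0.02, 0.0457), fell too, and COPS9 (0.17, SE 0.04, adjusted p = 0.0619) did not pass. In all 4 of 17838 genes were called by edgeR, against 1404 at an unadjusted p below 0.05. DESeq2 called 15, but it gave only 3035 genes an adjusted p, so the counts come from unlike sets of genes. All 4 edgeR calls were lower, but with the replicate number as a block 12 were called, 5 higher and 7 lower. The 4 calls were fragile. Leaving out replicate 2 of individual aptamers without Wnt, replicate 1 of individual aptamers with Wnt or replicate 1 of the dual aptamer with Wnt left 0 genes called, and IQGAP1 then had adjusted p = 0.147, 0.332 and 0.266. Without replicate 2 of the dual aptamer without Wnt 1 gene was called and without replicate 2 of individual aptamers with Wnt 2, where IQGAP1 had adjusted p = 0.105 and 0.173. DSP and MYH10 also lost their calls without replicate 2 of the dual aptamer with Wnt (adjusted p = 0.0806 and 0.0789). The count was 6 to 9 without replicate 1 or 3 of individual aptamers without Wnt (7 and 6), replicate 1 or 3 of the dual aptamer without Wnt (6 and 8), replicate 3 of individual aptamers with Wnt (8) or replicate 3 of the dual aptamer with Wnt (9).

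Averaged over the media, AXIN2 had a log2 fold change of 0.00 (95% confidence interval -0.08 to 0.09, adjusted p = 0.992), OGT of -0.06 (0.448), CTNNB1 of -0.04 (0.623) and OGA of -0.02. None of the 24 core Wnt targets was called by edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.365). Camera called 6 lists with the preset and none with an estimated correlation, where the smallest adjusted p was 0.637. Fry called none. The lists with the smallest p were cytosolic ribosomal proteins (median 0.03, adjusted p = 2.14e-12) and nuclear oxidative phosphorylation (0.04, adjusted p = 7.93e-06), each with adjusted p = 0.637 with an estimated correlation. Adjusted over the list alone, 2 ribosomal protein genes and 1 gene each of oxidative phosphorylation, the integrated stress response, p53 targets and TGF-beta and BMP targets were higher, and 2 G1/S genes were lower.

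The aptamer effects in the media were set against each other to ask whether they were alike. Of the 221 genes called without Wnt, 2.71% had the same direction with Wnt (95% Clopper-Pearson interval 1.00 to 5.82%, which treats genes as independent). Both comparisons called 148 genes, and every one of them, PTPRT, AGBL1 and CTNNA2 included, was higher with the dual aptamer without Wnt and lower with Wnt, against 2.41 genes expected in these directions if the calls were independent. Their median span was 605 kb. Across all tested genes the correlation of the log2 fold changes was r = -0.65 (rho = -0.07), and across the 10110 genes of at least 10 CPM it was r = 0.14 (rho = 0.18). Genes are not independent replicates.

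The test of the aptamer by Wnt interaction asks whether the aptamer effect itself differed between the media. The expressed Wnt targets did not pass it: AXIN2 was at -0.05 (95% confidence interval -0.21 to 0.12, adjusted p = 0.931), TNFRSF19 at -0.14 (0.745), LEF1 at 0.12 (0.679), NKD1 at -0.13 and ZNRF3 at -0.07. CTNNB1 was at 0.04 (0.871), OGT at -0.02 and OGA at 0.00. None of the 24 core Wnt targets was called by edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.917). The genes that passed were mostly the long, weakly expressed ones, such as PTPRT (-7.08, SE 0.56) and RBFOX1 (-5.89, SE 0.31). Of 17838 genes 360 were called by edgeR. Of these, 348 were higher with the dual aptamer without Wnt and lower with Wnt, 11 were the opposite and 1 had the same sign in both media. The interaction was positive for 12 and negative for 348, but without replicate 1 of the dual aptamer without Wnt for 129 and 385. Of the 10110 genes of at least 10 CPM 17 were called, among them MT-ND6 (0.14), and 1, lower, when the test was run on these genes alone. With the near-silent gene level subtracted, 35 genes were called by the span that no other gene overlaps and 93 by the whole span. Camera called 3 lists with the preset and none with an estimated correlation: mitochondrially encoded messenger RNAs (median 0.08, adjusted p = 4.63e-05, and adjusted p = 0.463 with an estimated correlation), ribosome biogenesis (0.06; 0.00952 and 0.756) and hypoxia and glycolysis (0.05; 0.0384 and 0.642). Adjusted over the list alone, 3 mitochondrially encoded messenger RNAs, 1 ribosome biogenesis gene and 1 PRC2 gene had a higher aptamer effect with Wnt. Fry called PRC2 genes and the Wnt pathway machinery (adjusted p = 0.0436 each).

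**Figure D4:**
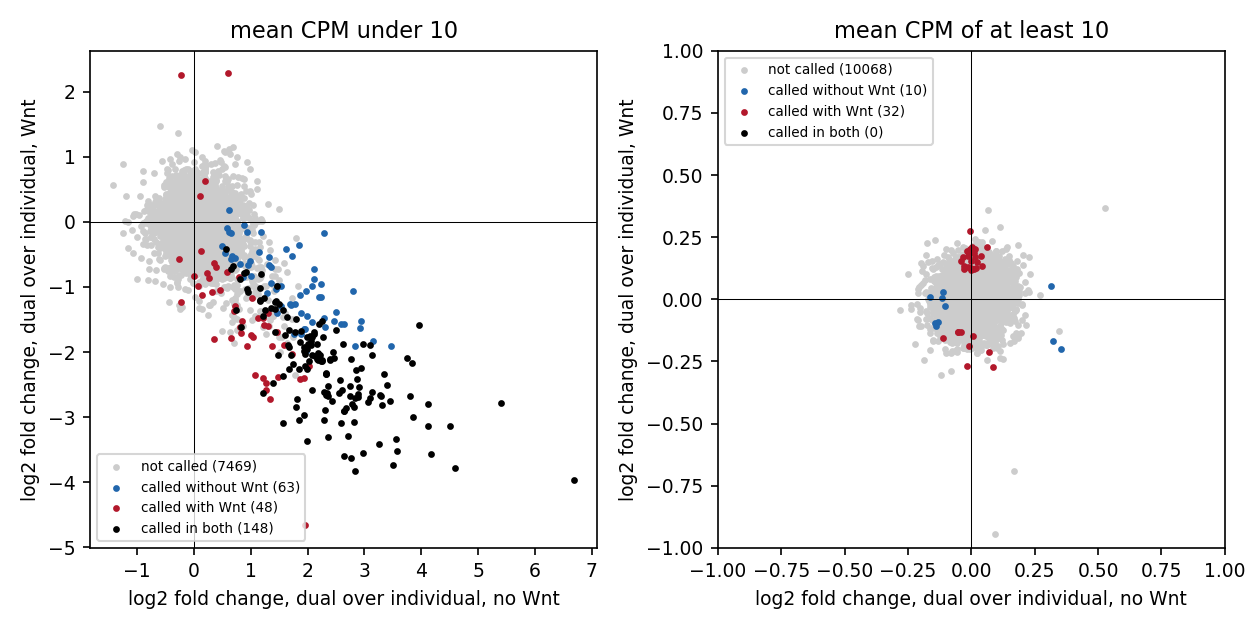
Log2 fold change of the dual over the individual aptamers without Wnt (x axis) and with Wnt (y axis) for genes with a mean below 10 CPM (left) and of at least 10 CPM (right), coloured by the medium in which edgeR called them. The 148 genes called in both media lie at lower right in the left panel, and none lies in the right panel.

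The authors' deposited tables give their own aptamer comparisons. In the authors' deposited table without Wnt, 95 genes had an adjusted p below 0.05, 88 higher and 7 lower with the dual aptamer, and in the one with Wnt 102 had, 13 higher and 89 lower. Of these, 90 and 100 were also called here, all in the same direction, and the log2 fold changes had r = 0.9998 and 0.9999 across 17838 genes, which are not independent replicates. The genes called in the authors' deposited tables had median spans of 614 and 616 kb. In the authors' deposited tables AXIN2 had a log2 fold change of 0.02 (SE 0.08) without Wnt and of -0.02 with Wnt, and PTPRT of 3.62 (SE 0.61) and -3.56 (SE 0.56).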

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

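The tests of DNA carry-over, unspliced RNA, exchanged labels, sequence bias and other medium factors below, the subtraction of near-silent level and the test of genes of at least 10 CPM alone were chosen only after the results were seen; the interaction test and the splits of the samples were planned.

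The aptamer effect differed between the media for 360 genes by edgeR's interaction test, for 35 with the near-silent gene level subtracted by own span, for 93 by whole span, and for 1 when only genes of at least 10 CPM were tested. Of the 80 splits of the samples tried, none but the real one called as many, the highest other calling 36 (a share of 1 of 80). This speaks only against a chance split of these libraries. Most other splits also mix libraries of different groups, which widens the spread they are tested against. Nothing in the labels shows separate cultures, so a chance difference between cultures is not excluded. Among the named genes, the interaction log2 fold change was -7.64 for AGBL1, -7.08 for PTPRT, -6.92 for LINC03000, -6.66 for NRG3, -6.23 for LRRC4C, -6.11 for CTNNA2, -5.89 for RBFOX1, -5.67 for SGCD, -5.66 for LUZP2, -5.59 for CDH18, -5.58 for SEMA5A, -5.54 for GALNT17, -5.54 for CA10, -5.53 for FRMPD4, -5.42 for CSMD1, -5.33 for RELN, -5.29 for CCDC26, -5.17 for LINC02055 and -4.66 for ADGRB3. Each of these genes was higher with the dual aptamer without Wnt and lower with Wnt. Smaller differences passed for SENP3 (0.28), TAF15 (0.21), UBE2M (0.20) and MT-ND6 (0.14). None of these 4 was called when only genes of at least 10 CPM were tested, and the call of MT-ND6 ended without replicate 2 of the dual aptamer without Wnt (adjusted p = 0.0653) and without replicates 1 and 2 of individual aptamers with Wnt (0.0888 and 0.0986).

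The first pattern is the higher count of near-silent genes, long ones in the called sets, in the dual aptamer libraries without Wnt and the individual aptamer libraries with Wnt. More unspliced nuclear RNA in the same groups cannot be told apart. Expressed genes over 200 kb lay -0.0042 (bootstrap SD 0.0019) from other expressed genes without Wnt and -0.0470 (SD 0.0026) with Wnt, short of the rise and the fall of 0.05 first asked for. The first minus the second, 0.0428 (SD 0.0033), has the sign that explanation needs, but DNA would add reads to long genes as well. Genomic DNA carry-over could account for it: near-silent genes on 23 of 23 chromosomes rose in both groups without overlap between libraries. In 1 comparison, 3 against 3 libraries separate by chance in either direction in 10% of cases. The chromosomes share the same libraries and so are no separate tests, and any source spread over the genome would raise all of them. The excess was uneven, from 0.952 CPM per megabase on chromosome 18 to 2.89 on chromosome 19 without Wnt, from 1.01 for own spans over 300 kb to 3.57 under 1 kb, and for olfactory receptor genes 1.102 per own span (635 genes) and 0.774 per whole span (858 genes), the whole-span level looked at first. An exchange of the aptamer labels in 1 medium cannot be told apart by the correlation of both aptamer comparisons over expressed genes (r = 0.14), which is too weak to decide, and an effect of the aptamer that depends on the medium also stays open, as untested.

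The second pattern is the small fall of genes such as IQGAP1, MYH10 and DSP with the dual aptamer averaged over media, where edgeR called 4. These 4 genes have long transcripts (7233 to 9796 bases against a median of 3921). Over expressed genes the aptamer effect had a Spearman rho of -0.31 with length and 0.37 with GC content, which offsets brought to -0.06 and 0.01. With gene span the rho was -0.35, and -0.16 was left with these offsets, which do not model span. The 4 genes had a median span of 135 kb, against 32.4 kb for all tested genes, so a bias tied to span stays open. With the GC and length offsets the median of the 4 genes was -0.11, still far over 2 SE from 0. The 4 genes were chosen by their small p in this same comparison, so that distance cannot decide on length and GC bias. MYH10 (-0.12 before, -0.11 after, SE 0.02 each, adjusted p = 0.0409) kept its call. DSP (-0.11 before, -0.10 after, SE 0.02 each, 0.0674) and IQGAP1 (-0.11 before, -0.10 after, SE 0.02 each, 0.0674) lost theirs, with fold changes that shrank by a larger share than their SEs. Chance cannot be excluded: 8 of 80 splits, the real one among them, called as many as the 4 genes. The others each exchanged most or all aptamer labels in 1 medium and so carry the interaction, which makes the share no rate of chance alone. The highest called 360. It exchanges all aptamer labels in 1 medium and so turns this comparison into the interaction, which points to a structure of the samples. A difference due to the aptamer stays open, as untested beyond this comparison.

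The third pattern is the change with conditioned medium of genes without a known Wnt role, such as the fall of EGR1 and FOS and the rise of HSPA8. Immediate early genes had a median log2 fold change of -0.72, as factors of the conditioned medium other than Wnt3A, or less fresh serum, might give. These and Wnt3A itself cannot be told apart, since every library with Wnt had conditioned medium and none had conditioned medium without Wnt3A. For the Wnt effect averaged over aptamers 7038 genes were called, against 360 in the highest of the other 79 splits (1 of 80). That split exchanges the medium labels of the dual aptamer libraries and so turns this comparison into the interaction. Here too the splits speak only against a chance split of these libraries, not against a chance difference between cultures.

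For the comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05. The real and the highest other split called 221 and 58 genes for the aptamer effect without Wnt, 228 and 0 with Wnt, 4792 and 0 for the Wnt effect with individual aptamers, and 5557 and 0 with the dual aptamer, all by edgeR.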

How the results depend on the processing

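The tests of genes of at least 10 CPM alone, of subtracted near-silent level, of GC and length offsets and of groups closer in near-silent level were chosen after seeing the data, as was DESeq2 beside the deposited tables; the whole-span subtraction was run first, and the own-span one was set after it because overlapped parts are not counted. Of 12962 values of called named genes under the alternatives, leave-one-out included, 11958 kept their direction and call, 1002 lost the call and 2 reversed; of 903 values of named genes not called, 5 became called and 81 reversed. Genes that an alternative filtered out or left without an adjusted p are not among these values and do not count as lost. For called named genes 561 values remained at 10 CPM or more alone and 655 with own-span subtraction, against 683 with DESeq2 size factors. Counts called moved over 1.5-fold as follows, and the cause was not tested except where fewer or more genes tested or a stricter threshold shows it. DESeq2 called 95 genes for the aptamer effect without Wnt, 102 with Wnt and 15 averaged over media, the last among only 3035 genes with an adjusted p. With no filter the counts were 401, 365 and 16 and the interaction had 800, and with the replicate block the averaged effect had 12. A 1.5-fold minimum left 851 for the Wnt effect with individual aptamers, 1161 with the dual aptamer, 725 averaged and 0 for the averaged aptamer effect (edgeR; 1404 at an unadjusted p below 0.05, and 15 by DESeq2 without that minimum). Genes of at least 10 CPM alone left 2 for the aptamer effect without Wnt, 0 with Wnt (edgeR, with 768 unadjusted), 1 for the interaction and 1 averaged over media. In the reported fit 10, 32, 17 and 4 genes of that level were called in that order. Leaving out the weaker genes does therefore not by itself account for the drop, and the adjusted p of the reported fit also depended on the p of those weaker genes. Subtraction by own span left 21, 19 and 35 for the aptamer effect without and with Wnt and the interaction, and by whole span 49, 51 and 93 and 1 averaged over media; GC and length offsets left 2 averaged over media. Individual aptamers with Wnt over the dual aptamer without Wnt gave 4623 against 7038. The share of same direction was 50% for genes of at least 10 CPM (10 genes called without Wnt) and 5.83% with the replicate block. Camera lists called moved to 3 (aptamer effect without Wnt) and 10 (interaction) with the offsets, to 7 for the interaction with the block and 8 with DESeq2 size factors; an estimated correlation left 0 without Wnt, 0 with Wnt, 0 averaged over media, 0 for the interaction, 8 for the Wnt effect with individual aptamers, 5 with the dual aptamer and 8 averaged, and fry gave 0 for the aptamer effect without Wnt, with Wnt and averaged. Leaving out 1 library at a time gave 169 to 291 genes for the aptamer effect without Wnt, 155 to 215 with Wnt, 0 to 9 averaged, 339 to 514 for the interaction, 3929 to 4369 for the Wnt effect with individual aptamers, 4459 to 5786 with the dual aptamer and 6450 to 7310 averaged. The core Wnt list's camera p then ran from 0.398 to 0.971, 0.498 to 0.976, 0.130 to 0.810, 0.705 to 0.948, 8.51e-22 to 5.68e-20, 1.59e-19 to 4.27e-18 and 5.29e-24 to 4.74e-21 in that order. Signs turned, with no call unless stated and the cause not tested, for CTNNB1 in the Wnt effect with individual aptamers (DESeq2 size factors -0.0048, upper quartile -0.019, DESeq2 -0.0067, no filter -0.0016, 6 libraries -0.0059, at least 10 CPM -0.0086, offsets -0.019), with the dual aptamer (upper quartile -0.0054) and averaged (upper quartile -0.012, at least 10 CPM -0.00045, dual with Wnt over individual without -0.021). They turned for LEF1 in the averaged aptamer effect (DESeq2 size factors -0.0034, upper quartile -0.0042, no filter -0.0071, at least 10 CPM -0.0017, own span -0.0023, whole span -0.00044, offsets -0.0091), OGA in the interaction (upper quartile -0.021, at least 10 CPM -0.019, own span -0.021, whole span -0.013) and with Wnt (offsets 0.0024), OGT in the interaction (no filter 0.0038, offsets 0.0086), TNFRSF19 (no filter -0.0015) and AXIN2 (no filter -0.0022, offsets -0.0032) in the averaged aptamer effect, NOTUM without Wnt (own span 0.0027, whole span 4.94e-05) and NKD1 with Wnt (offsets 0.012), and, of genes called in the reported fit, CTNNA2 (own span 0.40) and RPS12 (offsets 0.0072) in the Wnt effect with the dual aptamer, neither called there. With 1 library left out, signs turned for the aptamer effect without Wnt of TNFRSF19 (-0.015 to 0.15), LGR5 (-0.067 to 0.013), AXIN2 (-0.023 to 0.068) and NOTUM (-0.13 to 0.10), with Wnt of NKD1 (-0.075 to 0.0058), AXIN2 (-0.050 to 0.022) and NOTUM (-0.13 to 0.15), averaged of TNFRSF19 (-0.040 to 0.040), LEF1 (-0.025 to 0.018), AXIN2 (-0.022 to 0.025) and NOTUM (-0.078 to 0.072), for the interaction of AXIN2 (-0.089 to 0.0021), NOTUM (-0.13 to 0.16), OGT (-0.029 to 0.0042) and OGA (-0.012 to 0.022), and for the Wnt effect of CTNNB1 with individual aptamers (-0.016 to 0.0055) and NOTUM with the dual aptamer (-0.24 to 0.058). Whether replicate numbers pair the libraries stays unsettled: within-group residual correlations of libraries with the same number were above 0.1 in 5 of 18 pairs (highest 0.358), and 8 of 12 libraries correlated best on average with those of their own number. Depth limits changes in genes near the floor, and in the simulated data 18% of genes changed 1.1-fold were called.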

Other observations

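The gene sets in this part were put together only after the data, their members' changes with the conditioned medium included, were seen. Their tests, those of the aptamer effect included, are therefore not independent of the choice. The offsets below were also chosen after seeing the data. Targets of the aryl hydrocarbon receptor, which senses xenobiotics, rose with the conditioned medium averaged over aptamers: CYP1A1 by 3.49, CYP1B1 by 1.83 (counted over 14.7% of its span) and TIPARP, a feedback inhibitor of the receptor, by 1.56, while NQO1 (0.09, adjusted p = 0.345) and ALDH3A1 (-0.07, 0.772) did not pass. The median of the 5 tested genes was 1.56 (camera adjusted p = 6.32e-06 with an estimated correlation). Of 14 tested ERK feedback and ETS factor genes 11 rose and 2 fell, with a median of 0.77 (adjusted p = 9.88e-05 with an estimated correlation). ETV5 rose by 3.06, ETV1 by 2.10, IER3 by 1.24, DUSP4 by 0.97 and the ERK pathway inhibitors SPRED1, SPRY4 and SPRED2 by 0.85, 0.84 and 0.79, whereas SPRY2 (-0.11) and EPHA4 (-0.13) fell and the ERK phosphatase DUSP6 was at -0.09 (adjusted p = 0.591). The 11 rises came in libraries in which the immediate early genes EGR1 and FOS fell.

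Of 8 tested Notch targets 5 fell and 1 rose with the conditioned medium, with a median of -0.11 (adjusted p = 0.00319 with an estimated correlation). The transcriptional repressors HES5 (-2.33, at a mean of only 0.52 CPM over all libraries), HEY1 (-0.78), HES4 (-0.29) and HES1 (-0.11) fell and HEYL (0.15) rose. In the aptamer effect averaged over media the Notch targets as a set were higher with the dual aptamer, with a median of 0.04 (camera adjusted p = 0.000111 with the preset and 0.00962 with an estimated correlation, adjusted over these 3 sets). With offsets for GC content and transcript length the median was 0.01 and the adjusted p 0.0127 and 0.14998, so the shift did not hold with an estimated correlation. HES1 was at 0.11 (SE 0.02, adjusted p = 0.0619) and HEY2 at 0.20 (SE 0.04, 0.0759), which did not pass, and edgeR called no gene of these 3 sets. Of all tested genes 1404 had an unadjusted p below 0.05 by edgeR, and DESeq2 called 15 among only 3035 genes with an adjusted p.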
